A study of Meloidogyne incognita with 75 samples.

How the data were processed

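Counts of 75 single-nematode RNA-seq libraries of Meloidogyne incognita were analysed. Per the labels' protocols, individual animals were picked under a microscope, staged by morphology and lysed singly, and their messenger RNA was reverse transcribed, with pre_J2 hatched from eggs in vitro. Per the submitters' processing notes, HISAT2 2.2.1 and StringTie 2.2.1 were used. The genome build, annotation and further settings are not given in the sources used here. Both tables deposited by the authors hold whole-number counts per transcript, not normalized. Where such counts are derived from assembled coverage they are rounded estimates, which the values alone cannot show. The counting of near-identical gene copies, frequent in this polyploid genome, is not stated, so counts of a transcript with a close copy are uncertain. The strand setting is not given either. The full deposited table holds 45378 transcripts, 757 of them with 0 counts in every library, and 44267 genes by the first part of the identifier, with 1111 further transcripts of the same genes. The deposited filtered table holds 22287 transcripts with identical values, and a test on the file showed that it kept transcripts with a count in 56 or more libraries and dropped those with a count in 55 or fewer. Each column name equals a library title, and 0 columns were left unmapped.

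Groups were taken from the library titles. Each library is a separate individual by its title. No sequencing batch, date or plate is given in the labels, so a batch that goes with a stage cannot be told apart from the stage. Totals ranged from 3265447 to 40174566 counts. Smart-seq2 libraries carry no molecular identifiers, so counting intervals and floors cover counting error only.

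For each comparison of a pair of stages, edgeR 4.0.16 in R 4.3.3 was run on the libraries of those stages with filterByExpr, TMM normalization and the robust quasi-likelihood test. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, the first named stage being the numerator. Standard errors are the absolute log2 fold change over the square root of the F statistic. Levels are CPM over the library total, as mean ± SD, and log values are log2(CPM + 1). Stage-marking transcripts came from a single edgeR fit of all libraries, with the same thresholds in each of the 7 contrasts of a stage. Depth, detection and correlation were compared by permutation tests with 100000 resamples in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Libraries were compared with stage centroids by Pearson correlation over the 2000 most variable transcripts. Exact permutation tests were used for list levels. A fold against a stage without any count was computed from a floor of 3 counts over that stage, and ratios against 1 to 3 counts are given with a 95% exact interval.

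The named transcripts follow a rule fixed before the data were examined: per comparison, the 2 called with the smallest p in each direction among those with at least 1 CPM in 80% or more of the libraries of the higher stage, 1 per gene. Of the 3 per stage that the rule takes for stage-marking transcripts, at most 2 are printed. Gene lists on cuticle, moulting, cell wall enzymes, effectors, yolk, sperm, cell cycle, ribosome, muscle, neuropeptides, proteases, germline, nuclear receptors, stress, mitochondrial genes and host plant genes had been fixed as well. They needed names, which the files do not pair with the identifiers, so their tests and levels were not run, and markers of other material or of RNA quality were not analysed here.

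The pipeline was tested on simulated counts for each comparison, with the observed means, library sizes and dispersions and 200 transcripts changed. The share recovered at a 4-fold and at a 16-fold change was 1 and 30% for par_J2 against pre_J2, 45 and 79% for J3 against par_J2, 41 and 70% for J4 against J3, 33 and 73% for J4_moulting against J4, 18 and 62% for J4_female against J4_moulting, 12 and 67% for female against J4_female, 1 and 47% for male against J4_female and 1 and 49% for male against female. No simulated change was called in the wrong direction, and at most 5.93% of calls were false. Recovery depends on how many transcripts change, since the adjusted p is stricter when few do. In the real data 29.7% of the transcripts tested were called in male against female. The simulated shares therefore do not give the recovery in comparisons with many calls. The alternatives were DESeq2 size factors, no low-count filter, the deposited filtered table, a fit of all 75 libraries, DESeq2 1.42.0, limma 3.58.1 (voom with sample weights), the replicate number as a block, a library of low depth left out, counts summed to genes, no fold threshold and libraries left out in turn. Added after the data were seen were total counts without normalization factors, J4 replicates 7 and 8 left out because their columns stand between J3 columns in both deposited tables, libraries of the stages with 7 or 8 libraries left out in turn, and the filtered table or a pre_J2 library left out for stage-marking transcripts.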

Results

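The data came from single individuals of Meloidogyne incognita, the southern root-knot nematode, a parasite of plant roots that hatches from the egg as a juvenile, settles in the root and moults through further juvenile stages to the adult. RNA of each animal was amplified by a low-input Smart-seq2 protocol, which copies full-length messenger RNA from very small amounts of material. The 75 libraries fell into 8 stages by their titles, with 5 libraries of pre_J2, 12 of par_J2, 14 of J3, 8 of J4, 14 of J4_moulting, 8 of J4_female, 7 of male and 7 of female. The pre_J2 animals were hatched from eggs in vitro. The libraries titled male carried a stage tag that reads J4_male, and the labels do not say whether these animals had finished their last moult. The total count per library ran from 3265447 to 40174566 with a median of 15503915, and the stages differed in it (permutation test over the 8 stages, two-sided, p = 0.00416). Mean totals were lowest in J4, at 10927438 ± 3749509 (SD, n = 8), and highest in female, at 24013319 ± 12051054 (SD, n = 7). The table held 45378 transcripts. The files do not pair their identifiers with gene names, so transcripts are given by identifier and no gene group is described by function.

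J4 libraries held the most transcripts on average and pre_J2 libraries the fewest. At least 1 count was found for 33534 ± 3895 transcripts (SD, n = 8) in J4, 33095 ± 3962 (n = 14) in J4_moulting and 32404 ± 3074 (n = 14) in J3. The number was 30168 ± 4799 (n = 7) in female, 29459 ± 6190 (n = 8) in J4_female, 25832 ± 3342 (n = 7) in male, 24334 ± 3476 (n = 12) in par_J2 and 22710 ± 3183 (n = 5) in pre_J2. The stage means differed more than shuffled stage labels would give (permutation test, p = 1e-05, the smallest that 100000 resamples can give). The means of J4, J4_moulting and J3 lay closer together than the SD within each of them. With every library thinned to 3000000 counts, J4 still held the most, 32299 ± 3742, and pre_J2 the fewest, 21994 ± 3302. A few transcripts took a large part of the counts in some stages, the 50 most abundant holding 47.4 ± 8.41% (SD, n = 7) of the counts in female and 38.9 ± 4.22% (n = 5) in pre_J2, against 15.2 ± 3.56% (n = 12) in par_J2.

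The deposited filtered table held 22287 of the 45378 transcripts. It kept exactly those with a count in 56 or more of the 75 libraries, and its values equal those of the full table. This removed 44.2 ± 3.82% (SD, n = 5) of the counts of pre_J2, 30.3 ± 6.71% (n = 7) of those of female, 16.8 ± 6.13% (n = 7) of male and 15.5 ± 6.86% (n = 14) of J4_moulting, but only 2.84 ± 0.874% (n = 12) of those of par_J2 and 3.11 ± 0.828% (n = 14) of J3 (permutation test over the 8 stages, p = 1e-05, the smallest possible). The full table was therefore used for the comparisons.

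**Figure D1:**
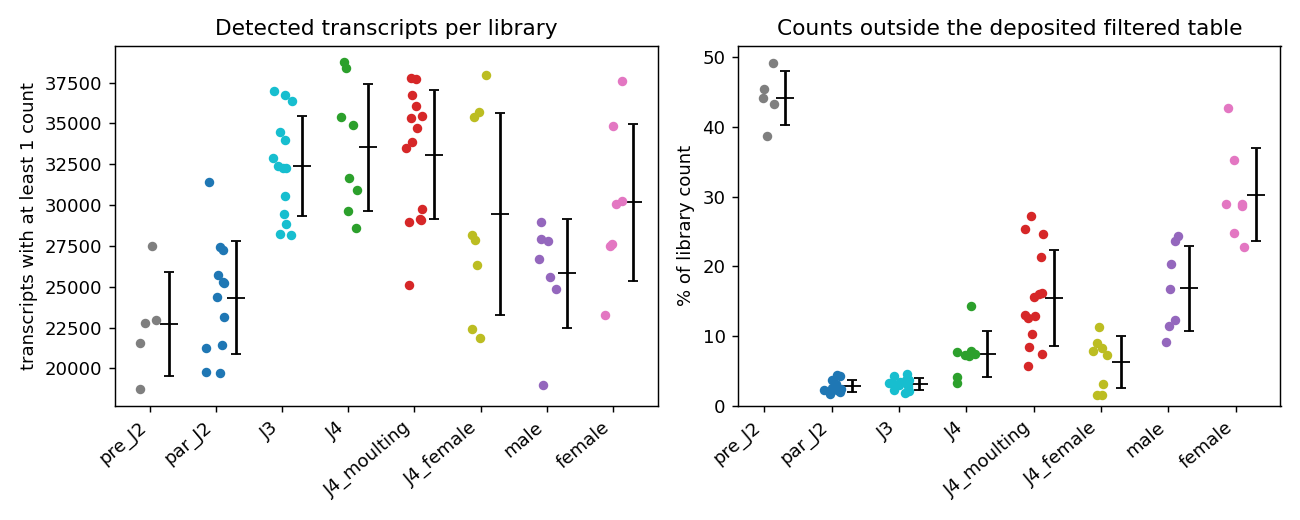
Left, transcripts with at least 1 count in each library by stage. Right, percent of each library's count that lies outside the deposited filtered table. Each point is 1 library, and the bar beside it is the stage mean with its SD. The 5 pre_J2 libraries lost between 38.7 and 49.3% of their counts, more than most other libraries, and the 12 par_J2 libraries between 1.70 and 4.45%.

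Taken over all stages together, libraries of the same stage resembled each other more than libraries of different stages. The median Spearman correlation was 0.810 within stages and 0.706 between them (permutation of the stage labels, p = 1e-05, the smallest possible). Within stages it was highest in female, 0.854, and J3, 0.834, and lowest in pre_J2, 0.656. The order did not hold for every stage. J4_female libraries correlated at 0.701 with each other, below their 0.776 with J3, 0.7505 with J4, 0.741 with J4_moulting and 0.734 with female. For par_J2 the median was 0.738 within and 0.763 with J3, and for J4 it was 0.7875 within and 0.798 with J3. Of the 75 libraries, 61 lay nearest the centroid of their own stage when each was left out of it. This was so for all 5 pre_J2, all 14 J4_moulting, all 7 male and all 7 female libraries, for 10 of 12 par_J2 and for 12 of 14 J3. It held for only 2 of the 8 J4 libraries, replicates 7 and 8, whose columns stand between those of J3 replicates 10 and 11 in both deposited tables. Of the other J4 libraries 3 lay nearest J4_female, 2 nearest J3 and 1 nearest par_J2. It held for 4 of the 8 J4_female libraries, and of the others 2 lay nearest J3 and 2 nearest J4. The assignment of single libraries depended on the transcripts used. With the 39623 transcripts that had 10 or more counts in at least 5 libraries, 61 libraries again lay nearest their own stage, 58 of them the same ones, among them 5 of the 8 J4, 3 of the 8 J4_female, 13 of the 14 J4_moulting and 9 of the 12 par_J2 libraries. No library was moved to another group on this ground. No pair of libraries of a stage agreed within sampling noise, the lowest chi-square per degree of freedom being 45.9.

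**Figure D2:**
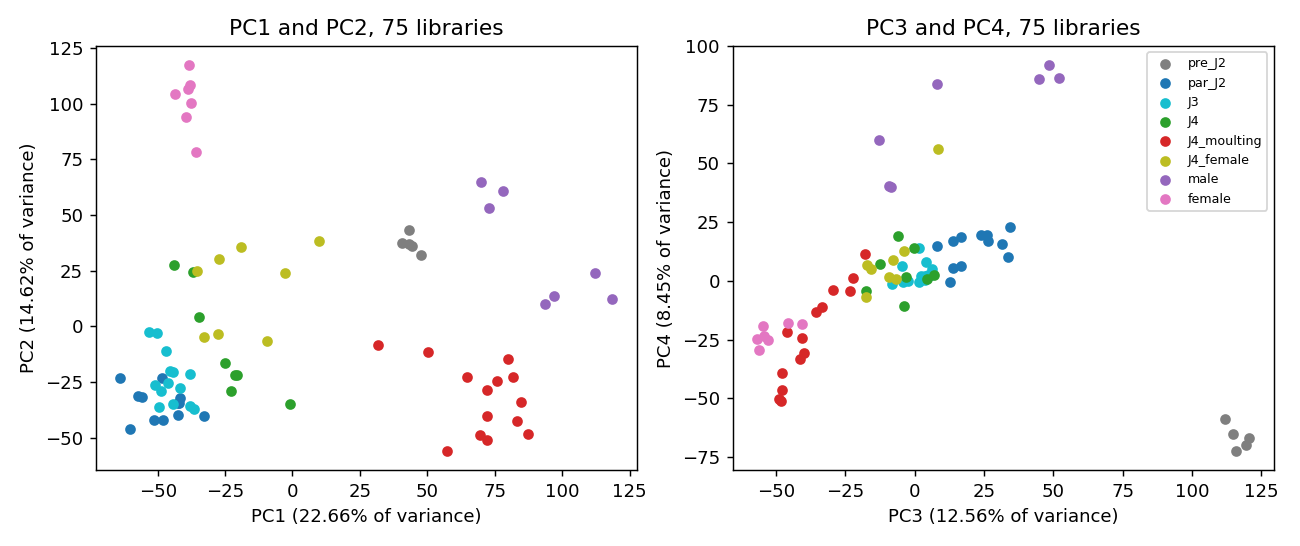
Principal components of log2(CPM + 1) of the 2000 most variable transcripts, each point 1 library coloured by stage. The axes give the share of variance, 22.66 and 14.62% on the left and 12.56 and 8.45% on the right. On the left, the libraries of pre_J2, J4_moulting, male and female lie away from those of par_J2, J3, J4 and J4_female. On the right, some J4_moulting libraries lie beside J4 and J4_female libraries, and J4_female replicate 8 lies near male libraries.

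The comparison of par_J2 with pre_J2 covered J2 animals hatched in vitro, pre_J2, and those that the labels call par_J2. Of 27241 transcripts tested, 3125 were higher and 1823 lower in par_J2. The 1823 transcripts held 60.4 ± 2.52% of all counts in pre_J2 (SD, n = 5) and 3.44 ± 0.695% in par_J2 (n = 12), while the 3125 held 48.2 ± 3.50% in par_J2 and 4.70 ± 0.666% in pre_J2, shares of transcripts that were chosen for this difference. Mi_30821.4 stood at 4024 ± 1604 CPM in pre_J2 and had 2 counts in all 12 par_J2 libraries together, a ratio of pooled levels of 417340 (95% exact counting interval 115530 to 3446100). Mi_12069.1 stood at 454 ± 160 CPM in pre_J2 and also had 2 counts in par_J2, a ratio of 49789 (13782 to 411140). In the other direction, Mi_10514.1 stood at 301 ± 144 CPM and Mi_04773.1 at 359 ± 193 CPM in par_J2, and neither had a count in any of the 5 pre_J2 libraries. Against a floor of 3 counts over the pre_J2 group, these were at least 6176-fold and 7382-fold higher. The edgeR adjusted p was 1.18e-14 for Mi_30821.4, 4.15e-13 for Mi_12069.1, 9.92e-10 for Mi_10514.1 and 1.27e-09 for Mi_04773.1. Scaling and filtering moved the balance of the calls, with 2284 higher and 2441 lower under DESeq2 size factors, 4176 higher and 1326 lower with total counts alone, and 2800 higher and 4415 lower without a low-count filter. A single fit of all 75 libraries called 13827 transcripts.

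The step from par_J2 to J3 showed fewer changes, most of them decreases. Of 25685 transcripts tested, 277 were higher and 737 lower in J3 than in par_J2. The increases were larger, with a median log2 fold change of 3.14 against -1.56 for the decreases, and the 277 transcripts held 19.2 ± 9.86% of the counts in J3 (SD, n = 14) and 2.87 ± 2.92% in par_J2 (n = 12). Mi_31818.1 was higher in J3 (log2 fold change 2.76, SE 0.43, adjusted p = 0.000666), at 17.3 ± 8.56 CPM against 2.93 ± 2.04, and so was Mi_24417.1 (6.34, SE 0.99, adjusted p = 0.000666), at 4.19 ± 4.22 CPM against 0.0368 ± 0.0668. Mi_33720.1 was lower (log2 fold change -3.10, SE 0.36, adjusted p = 2.02e-05), at 29.7 ± 14.8 CPM in J3 against 280 ± 205 in par_J2, as was Mi_01819.1 (-3.09, SE 0.36, adjusted p = 2.02e-05), at 24.9 ± 13.8 CPM against 237 ± 157. The direction of most calls depended on the fit: without a low-count filter 4925 transcripts were higher and 1218 lower, a single fit of all libraries called 3238 higher and 896 lower, DESeq2 called 1024 higher and 817 lower, and limma-voom 959 and 182. In simulated counts of this size and spread with 200 transcripts changed, 45% of transcripts changed 4-fold and 79% of those changed 16-fold were called.

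Between J3 and J4 almost no transcript passed the test. Of 30708 transcripts, 2 were higher and 0 lower in J4 by edgeR, although 4539 had an unadjusted p under 0.05. Mi_20168.1 was at 20.8 ± 16.4 CPM in J4 (SD, n = 8) and 2.97 ± 2.45 in J3 (n = 14; log2 fold change 2.54, SE 0.40, edgeR adjusted p = 0.0287). Mi_25443.1 was at 22.96 ± 17.3 CPM in J4 and 3.51 ± 1.88 in J3 (2.48, SE 0.41, adjusted p = 0.0313). In a single fit of all libraries neither passed (edgeR adjusted p = 0.465 and 0.289), nor did either without J4 replicate 5 (0.0684 for both) or Mi_25443.1 without J4 replicate 6 (0.0652). DESeq2 called 946 transcripts higher and 185 lower, limma-voom with sample weights called 708 and 94, and a fit with total counts alone called 356 and 2. Leaving out 1 J4 library at a time gave between 0 calls without replicate 5, the library of lowest depth, and 113 without replicate 4, with 81 without replicate 2, 6 without replicate 1 and 7 without replicate 3. In simulated counts with 200 transcripts changed, 41% of transcripts changed 4-fold and 70% of those changed 16-fold were called.

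Moulting J4 animals differed widely from J4. Of 32417 transcripts, 1651 were higher and 1106 lower in J4_moulting, and 803 of the increases were 10-fold or more. The 1651 transcripts held 24.97 ± 5.86% of the counts of J4_moulting (SD, n = 14) and 2.13 ± 0.855% of those of J4 (n = 8), and the 1106 held 2.72 ± 0.574% and 20.5 ± 7.73%. Mi_14308.1 stood at 115 ± 47.4 CPM in J4_moulting and 9.81 ± 6.03 in J4 (log2 fold change 3.93, SE 0.38, edgeR adjusted p = 5.22e-06), and Mi_32137.1 at 70.2 ± 43.1 CPM against 5.83 ± 4.01 (3.90, SE 0.41, adjusted p = 8.85e-06). Each was higher in all 14 moulting libraries than in any J4 library. Mi_14966.1 fell from 307 ± 329 CPM in J4 to 3.97 ± 3.87 (-6.40, SE 0.67, adjusted p = 8.85e-06) and Mi_17828.1 from 73.5 ± 45.9 to 7.05 ± 4.84 (-3.21, SE 0.34, adjusted p = 8.85e-06). DESeq2 called 4281 transcripts. The balance turned to 1181 higher and 1775 lower with total counts alone and to 1301 and 1464 by limma-voom.

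The stage titled J4_female was compared with J4_moulting. Of 32251 transcripts, 794 were higher and 1099 lower in J4_female, and 762 of the decreases were 10-fold or more. The 1099 transcripts held 26.4 ± 10.8% of the counts of J4_moulting (SD, n = 14) and 1.05 ± 0.333% of those of J4_female (n = 8). Mi_10781.1 stood at 263 ± 141 CPM in J4_female and 5.04 ± 5.89 in J4_moulting (log2 fold change 5.86, SE 0.61, edgeR adjusted p = 6.05e-06), and Mi_26504.1 at 347 ± 231 against 16.7 ± 11.99 (4.50, SE 0.48, adjusted p = 6.05e-06). Mi_37238.1 was lower, at 1.40 ± 0.713 CPM in J4_female against 39.7 ± 21.2 (-4.96, SE 0.48, adjusted p = 4.60e-06), as was Mi_15087.1, at 9.54 ± 3.25 against 150 ± 60.4 (-4.10, SE 0.41, adjusted p = 4.60e-06). The number of calls was 3266 by DESeq2 and 651 by limma-voom with sample weights. The balance turned to 1533 higher and 1154 lower in a single fit of all libraries, and it was 1016 and 1002 under DESeq2 size factors.

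More transcripts were higher than lower in female than in J4_female, by a margin that depended on the fit. Of 26006 transcripts, 950 were higher and 191 lower in female, and the 950 held 25.6 ± 9.65% of the counts of female (SD, n = 7) and 2.12 ± 0.356% of those of J4_female (n = 8). Mi_18049.1 rose from 0.0596 ± 0.145 CPM, 10 counts in all, to 193 ± 94.5 CPM (log2 fold change 12.23, SE 1.01, edgeR adjusted p = 5.56e-06). Mi_23574.1 stood at 131 ± 98.0 CPM in female, while the 8 J4_female libraries held 3 counts together, a ratio of pooled levels of 4670 (95% exact counting interval 1598 to 22648; edgeR adjusted p = 5.56e-06). Mi_14078.1 was lower in female, at 3.09 ± 1.73 CPM against 167 ± 237 (-4.72, SE 0.88, adjusted p = 0.00395), and so was Mi_04302.1, at 1.19 ± 1.42 against 34.0 ± 31.3 (-4.09, SE 0.78, adjusted p = 0.00459). The count was 642 in the deposited filtered table, 2802 by DESeq2 and 2908 by limma-voom, and it was 732 without female replicate 1 and 754 without female replicate 4. The number of lower calls was the less stable part. It was 46 without female replicate 1 and 44 without female replicate 4, but 393 without female replicate 6 and 507 without J4_female replicate 8. DESeq2 called 1496 higher and 1306 lower and a single fit of all libraries 765 and 529, and with total counts alone the balance turned to 551 higher and 5275 lower.

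The libraries titled male were compared with J4_female. Of 25450 transcripts, 1104 were higher and 583 lower in male, and 776 of the increases and 453 of the decreases were 10-fold or more. Mi_16932.1 stood at 216 ± 64.6 CPM in male (SD, n = 7) and 9.79 ± 7.06 in J4_female (n = 8; log2 fold change 4.85, SE 0.55, edgeR adjusted p = 0.000305), and Mi_40871.1 at 89.2 ± 40.2 against 7.21 ± 3.42 (3.94, SE 0.45, adjusted p = 0.000305). Mi_01134.1 stood at 120 ± 76.1 CPM in J4_female and had no count in any of the 7 male libraries, at least 6255-fold lower against a floor of 3 counts over the male group (edgeR adjusted p = 0.000203). Mi_36550.1 was at 88.5 ± 41.7 CPM in J4_female and 0.0765 ± 0.143 in male (-10.21, SE 1.07, adjusted p = 0.000203). The number of calls was 10274 in a single fit of all libraries, with 2840 higher and 7434 lower, 4197 by DESeq2 and 2782 by limma-voom, and with total counts alone 639 were higher and 680 lower, against 830 and 796 without a low-count filter. It was 948 without male replicate 6, and 845, 1043, 931, 1024 and 1100 without J4_female replicates 1, 2, 3, 5 and 6.

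The comparison of male with female gave the most calls of these 8 comparisons when each pair was fitted alone. Of 24617 transcripts, 4031 were higher and 3278 lower in male, which is 29.7% of those tested. The 4031 transcripts held 50.1 ± 11.3% of the counts of male (SD, n = 7) and 2.30 ± 0.794% of those of female (n = 7), and the 3278 held 5.20 ± 0.998% and 72.0 ± 5.40%. Mi_29970.1 stood at 86.6 ± 32.5 CPM in male and 1.47 ± 0.968 in female (log2 fold change 5.23, SE 0.42, edgeR adjusted p = 1.42e-05), and Mi_29458.1 at 147 ± 71.0 against 4.29 ± 2.00 (4.43, SE 0.38, adjusted p = 1.42e-05). Mi_04727.1 was lower, at 3.22 ± 1.81 CPM in male against 85.6 ± 30.02 in female (-5.53, SE 0.43, adjusted p = 1.42e-05). Mi_11129.1 stood at 55.1 ± 31.2 CPM in female and had 3 counts in the 7 male libraries together, a pooled ratio of 2572 (95% exact counting interval 880 to 12475; edgeR adjusted p = 1.42e-05). A single fit of all libraries called 4767 higher and 7116 lower, 11883 in all and fewer than the 13827 for par_J2 against pre_J2, a fit without a low-count filter 4954 and 5811, and limma-voom 4394 and 5256. With total counts alone 7195 were higher and 1788 lower.

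**Figure D3:**
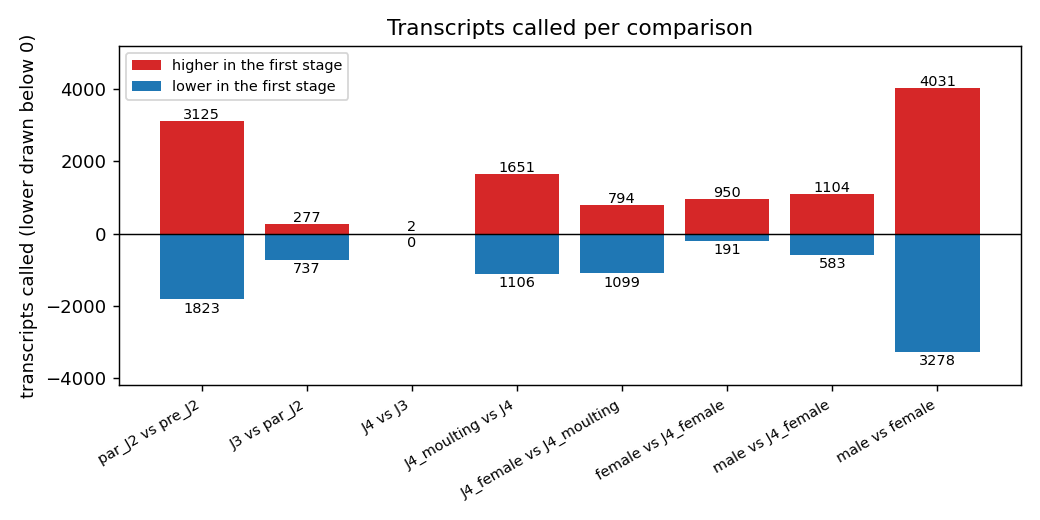
Number of transcripts called in each comparison (edgeR, adjusted p under 0.05 and at least a 2-fold change). Bars above 0 are transcripts higher in the first named stage and bars below 0 those lower in it. The comparison of male with female has the tallest bars, 4031 and 3278, and that of J4 with J3 has 2 and 0.

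Transcripts that mark a stage were sought in a single fit of all 75 libraries, as those higher than in each of the 7 other stages. Of 39835 transcripts, 1224 marked male, 628 pre_J2, 458 female, 312 J4_moulting and 83 par_J2. None marked J3, J4 or J4_female by edgeR, where 3, 11 and 49 transcripts had an unadjusted p under 0.05 and the same fold in all 7 contrasts. In this fit J4 against J3 gave 63 higher and 0 lower, so no transcript could mark J3. Fitted alone, J4_female against J4 gave 0 calls, so the rule leaves little room for markers of stages this alike. The 628 transcripts held 48.9 ± 4.67% of the counts of pre_J2 (SD, n = 5) and at most 1.75% in any library of another stage. The male transcripts held 23.5 ± 5.86% of the male counts (n = 7), the female ones 22.6 ± 9.17% of the female counts (n = 7), those of J4_moulting 15.2 ± 7.83% (n = 14) and those of par_J2 3.20 ± 0.982% (n = 12), shares that these transcripts were chosen for. In libraries of other stages, these 4 lists held at most 4.69, 1.40, 1.13 and 2.08%. The lowest par_J2 library held 1.42%, so the par_J2 shares overlap with those of other stages. Mi_28050.1 was at 142 ± 47.1 CPM in pre_J2 and at 0.0370 CPM in male, the next stage, and Mi_34926.1 at 1971 ± 2190 CPM against 0.138 in J4_moulting. Mi_01302.1 stood at 246 ± 131 CPM in male and 47.2 ± 20.3 in J4_moulting. Mi_01157.1 was at 20360 ± 15570 CPM in female and 12.1 ± 5.74 in J3. Of the male, female, J4_moulting, pre_J2 and par_J2 transcripts, 53.8, 58.5, 59.0, 49.4 and 20.5% are absent from the deposited filtered table. That table holds 22287 transcripts and lacks 23091 of all 45378, a set that includes transcripts not tested here. The share absent among the 39835 tested was not counted, so these shares are given without a baseline. The number for par_J2 was 37 at a log2 fold change of at least 2 and 20 under DESeq2 size factors.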

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

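The tests of the full male level, of depth, of the spread between J4 libraries and of shuffled stage labels in this part were chosen after the result was seen, and so was the condition that the gap in the test for RNA of moulting animals exceed the spread. The number of drawn splits per comparison was raised to 100 after 40 had been seen. Of 61 sets of libraries searched for a library far from the others, 4 were picked out, and chance, which picks about 1 in 20, would give 3.05, so these 4 are about what chance gives. The stages with the most libraries, par_J2, J3 and J4_moulting, were not searched.

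J4 replicate 2 had 14.323% of its counts outside the deposited filtered table, against 3.25 to 7.84% in the other J4 libraries. The same library held Mi_25443.1 at 1.29 CPM, against 11.65 to 52.7 CPM in the others. Male replicate 4 had 18969 transcripts with a count, against 24872 to 28988 in the other males. Female replicate 7 held Mi_18049.1 at 28.6 CPM, against 138.3 to 314.1 CPM in the other females.

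More transcripts were called in the same direction in J4_moulting against J4 and in male against J4_female than independent lists would share, although the comparisons have no library in common and the 1651 higher ones as a list did not pass in male (exact permutation test, adjusted p = 0.091). Of the transcripts tested in both, 213 were higher in both, where independent lists would share 55.5, and 231 were lower in both, against 20.9, while 3 and 2 moved in opposite directions. Under DESeq2 size factors the shared calls were 6.14 times the independent number, so the excess did not hinge on TMM. These factors kept 90.8% of the main calls for J4_moulting against J4 and 84.5% for male against J4_female. A composition effect that both scalings share therefore cannot be decided by this test. An excess of shared calls was not particular to this pair of comparisons. Of transcripts higher in J3 than in par_J2, 57 were lower in male than in J4_female, where independent lists would share 5.47. For those higher in par_J2 than in pre_J2 these numbers were 271 and 62.85. Over 1920 transcripts higher in every male than in every female library, no J4_moulting library reached the male level. The highest had a mean log2(CPM + 1) of 4.177, and the lowest male 4.99 (SD over males 0.274). These transcripts were chosen for their level in the same males, which raises the male values. J4_female replicate 8 stood at 4.241, above every J4_moulting library. The test therefore cannot decide whether animals at the full male level were among the moulting libraries. That question stays open, and earlier male development in some moulting animals and a moult common to both stages remain open and untested.

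Male libraries differed among themselves in the 1651 transcripts that are higher in J4_moulting than in J4, whose mean log2(CPM + 1) was 4.04, 2.30, 2.22, 1.78, 3.81, 3.62 and 3.75 in male replicates 1 to 7, and 2.84 was the highest in J4_female. The number of counts is argued against, since thinning to 3000000 counts moved the level of a male library by at most 0.0177 against a range of 2.26, and replicate 7, with the fewest counts (17927727), stood at 3.75. Thinning does not test the amount of RNA or its amplification. RNA of moulting animals would bring the members in their J4_moulting proportions, and of 458 members with a mean of at least 100 CPM in J4_moulting, 26% or more lay over 10-fold below the library's median ratio to J4_moulting in each male, against 10.5 to 22.9% in the J4_moulting libraries. That gap is smaller than the SD of 3.84 between the latter, and the males' own expression also moves the ratio, so this stays open. Different times around the last moult may underlie the values, and no label gives the time.

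Only 2 transcripts were called between J4 and J3. The common dispersion of the 8 J4 libraries was 0.917, above every one of 40 draws of 8 J3 libraries (highest 0.815). A spread common to all J4 libraries did not prevent calls as such. The comparison of J4_moulting with J4 used the same 8 J4 libraries and gave 2757 calls. Whether the spread hid smaller changes between J4 and J3 cannot be told from other comparisons, whose differences may be larger. The common dispersion in J4 against J3, 0.775, and that of the J4 libraries with any 1 left out, at most 0.986, lay below the 1.02 to 2.24 of the other comparisons. Of simulated 16-fold changes, 70% were recovered. The simulation gave both stages the same dispersion per transcript and held no library that stands apart, so it does not cover single J4 libraries as a cause. The number of calls rose to 113 without J4 replicate 4 and 81 without J4 replicate 2, and it was 0 without J4 replicate 5. DESeq2 called 1131 transcripts and limma-voom with sample weights 802, so a part of single libraries or of the fit in the low number stays open. Of 101 splits of the 22 libraries, 5 gave as many calls, the real one included, a share under 0.05 by less than 1 split, and others called 10, 25 and 80, which may come from a structure of these libraries that was not tested, so chance is not taken as excluded for the 2 calls.

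For the other comparisons chance regrouping can be excluded, since in each only 1 of 101 splits, the real one, gave as many calls. The highest number among the others was 20 for par_J2 against pre_J2 (4948 in the real split), 0 for J3 against par_J2 (1014), 55 for J4_moulting against J4 (2757), 104 for J4_female against J4_moulting (1893), 1 for female against J4_female (1141), 1 for male against J4_female (1687) and 2 for male against female (7309). Shuffled stage labels gave 0 stage-marking transcripts in each of 20 draws, against 2705 for the real labels, so that 1 of 21 gave as many.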

How the results depend on the processing

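Settings with total counts only, with libraries of the stages of 7 or 8 libraries left out, with J4 replicates 7 and 8 left out, and with the filtered table or a pre_J2 library left out for stage-marking transcripts were chosen after seeing the data. Every total of calls kept within 1.5 times its value except those given here, and the cause was not tested. A total shows neither the balance of higher and lower calls nor whether the same transcripts were called. Limma-voom called 1141 transcripts for J3 against par_J2, but these held only 31.9% of the 1014 main calls. It held 54.6% of the main calls for J4_moulting against J4 and 26.3% for J4_female against J4_moulting. In the other comparisons it held between 73.2 and 100%. A single fit of all 75 libraries called 13827 transcripts for par_J2 against pre_J2, 4134 for J3 against par_J2, 63 for J4 against J3, 10274 for male against J4_female and 11883 for male against female. DESeq2 called 1841 for J3 against par_J2, 1131 for J4 against J3, 4281 for J4_moulting against J4, 3266 for J4_female against J4_moulting, 2802 for female against J4_female and 4197 for male against J4_female. Limma-voom called 802 for J4 against J3, 651 for J4_female against J4_moulting, 2908 for female against J4_female and 2782 for male against J4_female. Without a low-count filter there were 6143 for J3 against par_J2 and 4 for J4 against J3. The deposited filtered table, which tests fewer transcripts, gave 642 for female against J4_female and 10 for J4 against J3, and for stage-marking transcripts 22 in par_J2, 131 in J4_moulting, 563 in male and 220 in female. For J4 against J3 there were also 10 under DESeq2 size factors, 0 with the low-depth library left out, 4 without J4 replicates 7 and 8 and 358 with total counts only, which gave 5826 for female against J4_female. The par_J2 stage-marking number was 37 at the higher fold threshold and 20 under DESeq2 size factors.

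With the replicate number as a replicate block, the calls were 2166 for par_J2 against pre_J2, 341 for J3 against par_J2, 0 for J4 against J3, 836 for J4_moulting against J4, 874 for J4_female against J4_moulting and 892 for male against J4_female, and the other comparisons stayed within 1.5 times. The numbers name separate animals. Same-numbered libraries did not deviate together, their mean correlation lying between -0.0152 and 0.0329, and at most 2 libraries of a comparison correlated best with their own number.

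Leaving out 1 library at a time gave 3932 to 4315 calls for par_J2 against pre_J2, 0 to 113 for J4 against J3, 732 to 1496 for female against J4_female and 845 to 1886 for male against J4_female. DESeq2 size factors moved the median log2 fold change of all tested transcripts by between -0.46 (par_J2 against pre_J2) and 0.15 (J4 against J3), and total counts only by between -1.05 (female against J4_female) and 0.88 (male against female), so changes near these sizes depend on the scaling. Of 275 values of named transcripts under other settings, 268 kept their direction and call, 7 kept the direction alone (Mi_20168.1, Mi_25443.1 and, with the block, Mi_14078.1) and 0 reversed. With 1 library left out these were 273, 3 and 0 of 276. The named transcripts have the smallest p in the main fits, so these numbers do not describe the calls in general. Differences in detection and within-stage correlation kept their side under the settings tried, and the number of libraries nearest their own stage was 61 under both, 58 of them shared. For the counts of calls, depth was tested by leaving out J4 replicate 5, the library with the fewest counts, and for detection by thinning. Gene list tests were not run.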

Other observations

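The comparisons and tests in this part were chosen after the data were seen. A few transcripts were very abundant in some stages. Mi_00245.1 took 60345 ± 21315 CPM in pre_J2 (SD, n = 5) and no more than 8.3 CPM on average in any other stage, and Mi_28065.1 took 25292 ± 18233 CPM in female (n = 7) against 2.5 CPM or less on average in each other stage. Mi_00696.1 was the most abundant transcript in J3, at 83078 ± 68525 CPM (n = 14), and stood at 29177 ± 31634 CPM in J4_female (n = 8). It stood at 21715 ± 33919 CPM in J4 (n = 8), where 1 library held 91936 CPM, and at 8739 ± 17303 CPM in par_J2 (n = 12), where 1 library held 62440 CPM.

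The lists found in 1 comparison were followed in stages that had not entered it, with exact permutation tests, two-sided, adjusted over 8 tests. Levels are CPM over the library total. With library totals alone, the median log2 fold change of all tested transcripts against J4_female, taken without the added 1, was -0.26 in male and -1.28 in female. The 1106 transcripts lower in J4_moulting than in J4 had a mean log2(CPM + 1) of 2.24 ± 0.0916 in male (SD, n = 7) and 4.14 ± 0.399 in J4_female (n = 8), lower in 7 of 7 males than in any J4_female (exact p = 0.000155, adjusted 0.000414). The 3125 transcripts higher in par_J2 than in pre_J2 were lower in male, 3.45 ± 0.365, than in J4_female, 4.35 ± 0.246 (7 of 7 libraries, exact permutation p = 0.000155, adjusted 0.000414). In female they stood at 3.54 ± 0.258 (adjusted exact p = 0.000414) and the 1651 transcripts higher in J4_moulting at 1.76 ± 0.277, against 2.37 ± 0.302 in J4_female (adjusted exact p = 0.000932). List levels and the shift of all transcripts are on unlike scales, so whether any list changed in female beyond that shift cannot be told. The 1651 stood at 3.08 ± 0.936 in male and the test did not pass (exact permutation p = 0.0637, adjusted 0.091). Nor did it pass for the transcripts lower in J4_moulting in female, 3.78 ± 0.260 (exact permutation p = 0.0682, adjusted 0.091), or for those higher in pre_J2, at 2.34 ± 0.310 in male, 1.84 ± 0.311 in female and 2.24 ± 0.648 in J4_female (adjusted exact p = 0.699 and 0.188).

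The transcripts higher in pre_J2 than in par_J2 took very different shares of the counts of single males. In male replicates 1 to 7 the share was 4.38, 38.7, 30.2, 31.8, 5.49, 7.24 and 6.14%. Mi_25779.1 and Mi_42693.2, singled out after their values were seen, made up 18.3, 11.15 and 13.98% of the counts of replicates 2, 3 and 4 and 0.0286% or less in each other male library. Without this pair the shares in replicates 1 to 7 were 4.35, 20.4, 19.02, 17.9, 5.48, 7.24 and 6.13%.

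J4_female against J4 gave 0 calls in either direction among 28250 transcripts by edgeR, 1360 having an unadjusted p under 0.05, while DESeq2 called 0 higher and 3 lower and limma-voom called 0. Male against J4_moulting gave 3417 higher and 5212 lower of 31948 transcripts by edgeR, 3493 and 8717 by DESeq2 and 3793 and 7467 by limma-voom.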
